A study of Mus musculus with 61 samples.

How the data were processed

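The series profiled NIH/3T3 mouse fibroblasts before and after heat shock, or with LNAs against B2 RNA or Ezh2, by ChIP-seq of Ezh2, Suz12, H3K27me3 and Pol II S2P, by B2 CHART-seq with 2 probes and by short RNA sequencing. Samples were grouped by the conditions that their labels name. Where only replicate numbers tell samples of a group apart, p-values rest on the spread between those samples, which edgeR shares across regions as given below.

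The authors deposited 24 lists of aligned reads, 1 line per read with its position, strand and mapping quality, a score from 0 to 60 that was used only to filter reads. Per the submitters' processing notes, the genome build was mm9 and the tools were cutadapt, BWA, TopHat2 2.1.0, Bowtie, bedtools and SICER, with no role or order given. What the authors' filter of the deposited reads kept is not given in the sources used here. The reads lay in separate clusters with empty sequence between them, so a region without reads is not a measured zero, and the total of a file is not the depth of its library. Both mates of a pair can be listed, so counts are of reads, not fragments.

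In each ChIP list, 42.0 to 89.6% of the reads lay in 2 stretches, on chromosome 2 (98500001 to 98510000) and chromosome 9 (3000001 to 3040000), which left 25352 to 482280 reads elsewhere. In the CHART lists these stretches held at most 0.000794% of reads. Reads sharing position and strand with another were 54.0 to 96.5% of the ChIP reads. In CHART probe 1 they were 69.7% and 3.69% before heat shock and 36.2% and 0.608% after it, and in probe 2 55.0% before and 87.1% after. Mapping quality was 0 for 21.8 to 56.8% of ChIP reads.

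The authors deposited 11 profiles of short RNA 5′ ends at positions -5 to 120 of B2 RNA. Per the file headers, the ratio in each 50-nt fibroblast profile was the read count at a position over tRNA-longB2 RNA counts in the files before and after heat shock, and over tRNA counts in the LNA files. How tRNA and long B2 RNA were combined is not given in the sources used here. Levels were compared only between files whose headers name the same kind of divisor. Per the file headers, the ratio in the ES profile and the signal in the 6 longer-read profiles were read counts over the count at position 1. Each 50-nt fibroblast profile pools both libraries of its condition. In the longer-read profiles every value was a whole multiple of 1 read within a tolerance of 0.001 (100% of values), which gave 568, 1070, 906 and 2746 reads for the libraries before and after heat shock, 1428 for the B2 LNA and 90 for the Ezh2 LNA. For the second library after heat shock and the Ezh2 LNA library too few low values were present for a formal recovery, so their read numbers rest on the assumption that position 1 held a whole number of reads.

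Reads were counted by their midpoint in 10 kb bins. Genes would have been the regions, but the gene table used here is on assembly GRCm38.p6 and coordinates were not converted between builds, so no gene was assigned to a bin. The 13 gene lists (260 genes) fixed before the data were examined were therefore not used. Tests, samples, windows and the first set of alternatives were also fixed before the data were examined. edgeR 4.0.16 in R 4.3.3 kept bins by filterByExpr, normalised by TMM and tested with the quasi-likelihood F test at a Benjamini-Hochberg adjusted p of 0.05. Ezh2, Suz12, H3K27me3 and CHART probe 1 were fitted with their 4 libraries each and Pol II S2P with all 6. For Suz12, H3K27me3 and CHART probe 1, edgeR gave the spread shared across bins infinite weight. Their p-values in bins therefore do not reflect how far the libraries of a group differ in the bin itself. DESeq2 1.42.0 was the alternative tool. Up to 5 regions per direction could be named, those past the threshold with the largest absolute log2 change, above-median abundance and both libraries of a group above or below both of the other, with adjacent bins merged. Only some of them are given. For probe 2, bins with at least 10 reads over both libraries were compared on log2(CPM + 1), CPM being computed here from the file's reads.

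After the bins had been seen, the test was repeated within stretches listed in both conditions, where islands of both conditions overlapped. These covered 1.22 Mb for Ezh2, 1.99 Mb for Suz12, 1.74 Mb for H3K27me3, 1.30 Mb for Pol II S2P after heat shock, 3.62 Mb for Pol II S2P with the B2 LNA and 14.0 Mb for CHART probe 1. Restricting to such stretches keeps only places that passed the filter in both conditions, so a complete loss or gain is not seen there.

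Each fit was tested on simulated data with known changes. Within the shared stretches, a 4-fold change was recovered in 30.4% of 23 regions for Ezh2, 45.5% of 44 for Suz12, 16.7% of 6 for H3K27me3, 46.2% of 13 for Pol II S2P after heat shock, 28.6% of 28 with the B2 LNA and 4.44% of 45 for CHART. A 16-fold change was recovered in 66.7% of 18, 92.9% of 42, 100% of 6, 84.6% of 13, 90.9% of 33 and 85.7% of 49. The simulations ran on 314, 624, 108, 203, 590 and 10152 stretches. For single positions of B2 RNA, a 2-fold change was recovered in 0 of 6 positions and a 4-fold change in 40% of 5, simulated on 36.

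Replicate number coincided for most reads with the sequencing run or instrument for Ezh2, H3K27me3, Pol II S2P and CHART probe 1, which left 1 library per group in each run, too few for a value within a run. All Suz12 libraries came from 1 lane. Islands were merged runs of reads with gaps of at most 600 bp. Overlaps needed at least 1 bp (bedtools 2.31.1) and were compared with 20 shuffles. Short RNA shares used the windows 1 to 5 (start), later positions (internal) and 95 to 101, with exact Clopper-Pearson 95% intervals where reads were recovered. Profile distance was the share of ends that would have to move to turn a profile into another. Libraries were compared by exact two-sided permutation (scipy 1.17.1), for which 2 against 2 allows no p below 0.333. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, limma 3.58.1 and the R package data.table, version 1.17.8.

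Alternatives were DESeq2, no TMM, other low-count filters, 5 and 50 kb bins, 1 read per position and strand, a replicate block, leaving out each library, the 4 Pol II libraries compared alone, other island gaps and minimum reads, other windows along B2 RNA and probe 2 for probe 1. Added after seeing the data were reads of mapping quality 20 or more, leaving out the stretches on chromosomes 2 and 9, the stretches listed in both conditions, bins with reads in every library, regions with reads in both conditions of both assays or probes, probe 2 in 50 kb bins, among called bins or with duplicates removed, the crossed block, left-out libraries on the bins tested with all libraries, and the test per position of B2 RNA.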

Results

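B2 RNA is a short noncoding RNA transcribed from a family of short interspersed elements of the mouse genome, and the series followed it through a heat shock of NIH/3T3 mouse fibroblasts. Cells carrying a scrambled locked nucleic acid (LNA, a modified antisense oligonucleotide) stayed at 37 °C or were moved to 45 °C for 15 minutes, and these states are called before and after heat shock. Other fibroblasts received an LNA against B2 RNA at 500 nM or an LNA against Ezh2 at 25 nM for 24 h, and the labels do not say whether those cells were heated. Undifferentiated mouse embryonic stem (ES) cells gave 1 more short RNA library. The series text calls its 2 libraries per condition biological replicates.

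Of the 61 samples, the 24 lists of aligned reads and 11 profiles of short RNA ends were analysed. The lists covered 18 libraries of chromatin immunoprecipitation (ChIP) and 6 of CHART, in which oligonucleotide probes pull down an RNA together with the chromatin it lies on. Each ChIP list held 117426 to 3213842 reads, with 729668 to 2699444 for Ezh2, 1907625 to 2621100 for Suz12, 117426 to 3213842 for the histone mark H3K27me3 and 705102 to 1745855 for RNA polymerase II phosphorylated at serine 2 of its tail (Pol II S2P). The CHART lists held 1094429 to 5606116 reads. Input, negative-probe and RNA-seq libraries were not analysed here, so no background of that kind stands beside the values.

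Short RNA was sequenced to learn where along B2 RNA its fragments begin. In the 50-nt reads, 5′ ends inside B2 RNA (positions 6 to 120) made up 86.8% of all ends after heat shock and 72.0% before it. Ends in the start window (positions 1 to 5) were 5.73% after and 14.6% before. Ends in a window around position 98 (that position and 3 on either side) were 34.4% after and 15.6% before, and the ratio of ends at position 98 to ends at position 1 was 3.93 after and 0.635 before. Relative to the divisor that both file headers name, tRNA-longB2 RNA counts, position 98 stood at 5.28 after heat shock and 2.57 before (2.06-fold higher) and position 97 at 4.85 and 2.01 (2.41-fold higher). Position 1 stood at 1.34 and 4.04 (3.01-fold lower), while all internal positions together differed 1.05-fold. The headers do not say how tRNA and long B2 RNA were combined in that divisor, and whether it stayed level through heat shock is unknown, so these folds are relative to it alone. The 5 internal positions with most ends were 98, 97, 99, 32 and 103 before heat shock and 98, 97, 99, 77 and 96 after it. Each of these profiles pools both libraries of its condition and whole reads were not recovered from it, so no replicate spread or interval goes with these shares.

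**Figure D1:**
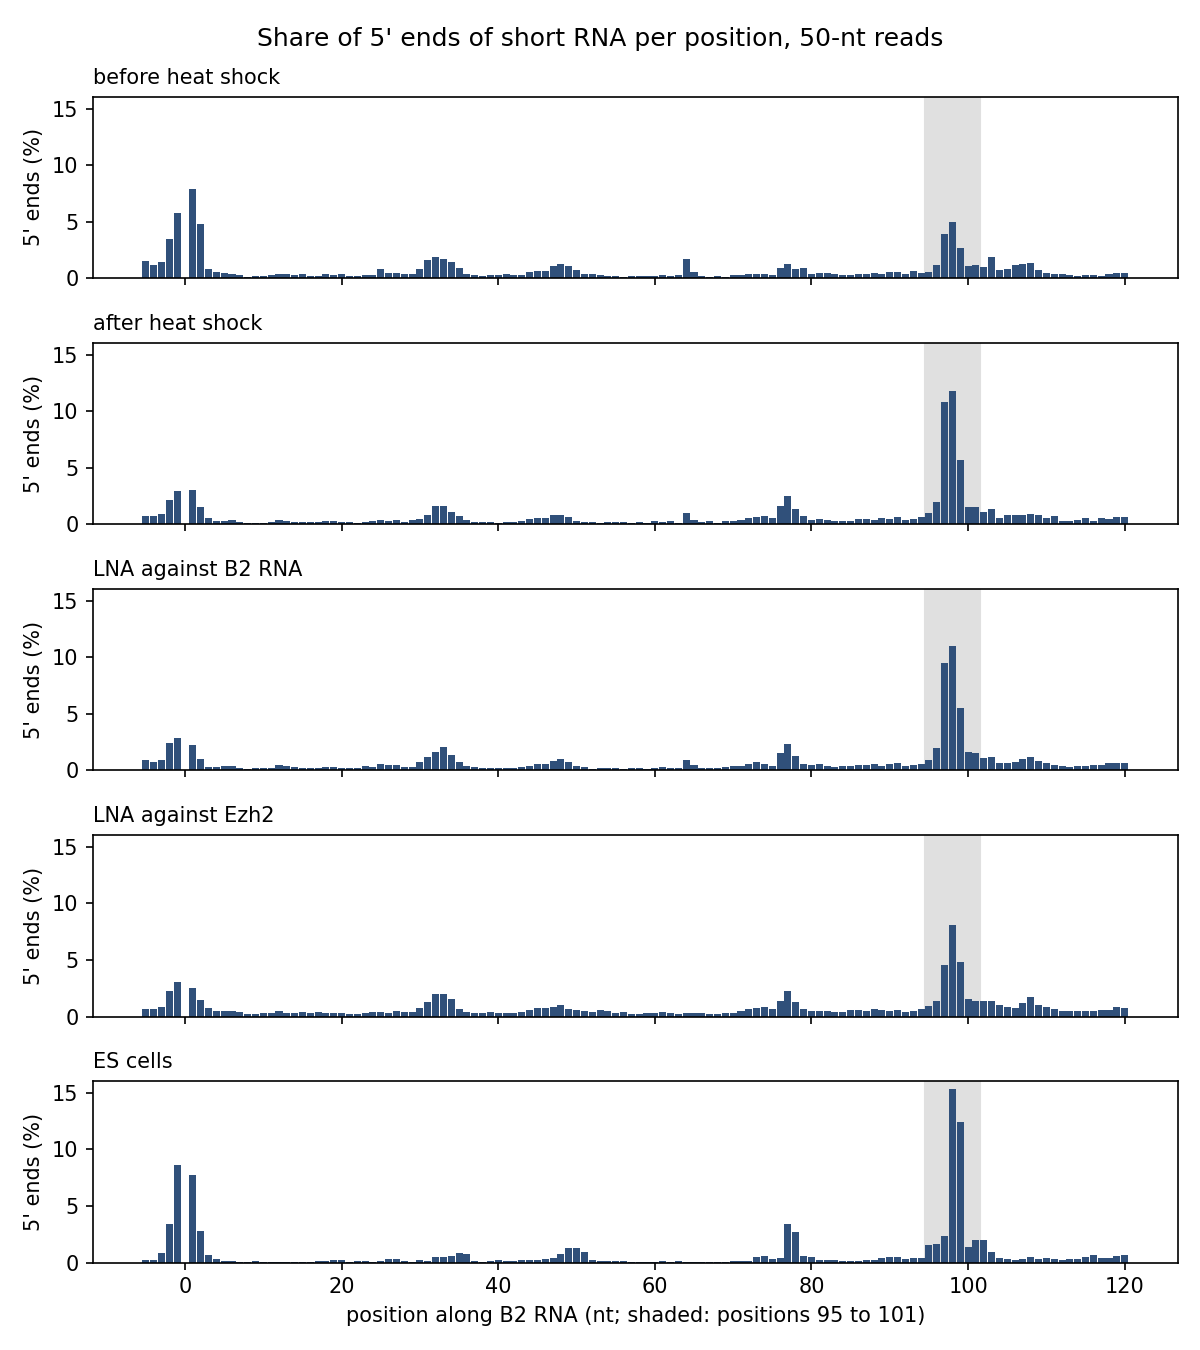
Share of short RNA 5′ ends (percent of all ends, vertical axis) at each position along B2 RNA (nt, horizontal axis) in the 50-nt reads, 1 panel per condition, with the window around position 98 shaded. That window holds 15.6% of ends before heat shock, 34.4% after it, 32.0% with the LNA against B2 RNA, 22.7% with the LNA against Ezh2 and 36.8% in ES cells.

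Longer reads of up to 200 nt from the same short RNA libraries gave a value per library, so they are not independent of the 50-nt profiles. Internal ends were 86.1% ± 0.831 (SD, n = 2) after heat shock and 71.6% ± 7.80 (SD, n = 2) before it, a difference of 14.5 percentage points. Both libraries after heat shock (86.6% and 85.5%) lay above both before it (77.1% and 66.1%), and an exact two-sided permutation test gave p = 0.333, the smallest p this design allows. Ends in the window around position 98 were 27.5% ± 11.8 after and 15.5% ± 0.272 before (SD, n = 2 each), again with an exact permutation p = 0.333. The libraries after heat shock stood at 19.2% (95% interval 16.7 to 21.9%, 906 reads) and 35.8% (34.0 to 37.7%, 2746 reads), against 15.3% (12.5 to 18.5%, 568 reads) and 15.7% (13.6 to 18.0%, 1070 reads) before it. These Clopper-Pearson intervals cover counting error only. Among internal ends alone, the share of that window was 22.2% and 41.9% after heat shock and 19.9% and 23.8% before it (exact permutation p = 0.667), and without the second library after heat shock the difference in means was 0.353 points. Per position, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment passed 0 of 27 positions, with 2 at an unadjusted p under 0.05 (no other tool was run). Those were positions 1 and 2, with log2 changes of -1.57 and -1.78 and an adjusted p = 0.203 for both. Positions 97, 98 and 99 had log2 changes of 1.03, 0.80 and 1.11. In simulated data a 2-fold change was recovered at 0 of 6 positions, so changes of that size could have been missed.

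**Figure D2:**
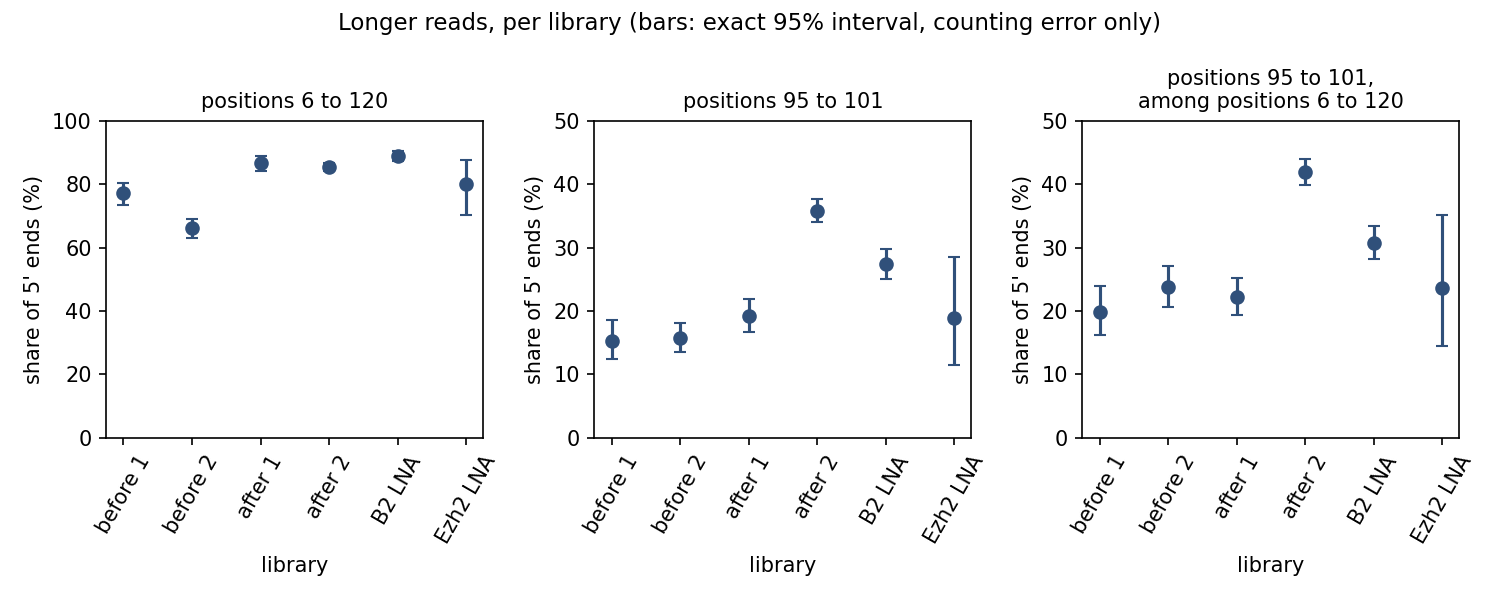
Share of 5′ ends (percent, vertical axis) per longer-read library (horizontal axis) in positions 6 to 120, in the window around position 98, and in that window among ends at positions 6 to 120, with bars for the exact 95% interval, which covers counting error only. For the window around position 98 the libraries before heat shock stand at 15.3% and 15.7%, and those after it at 19.2% and 35.8%.

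LNAs against B2 RNA and against Ezh2 were used to ask how the ends along B2 RNA depend on either. Relative to tRNA counts, the divisor named for both LNA files, all ends along B2 RNA came to 87.7 in the file labelled B2 LNA and 34.0 in the one labelled Ezh2 LNA (2.58-fold), and position 98 to 9.63 and 2.74 (3.51-fold). No file of control cells has that divisor, so whether either LNA lowered its target was not measured here. With the LNA against B2 RNA, internal ends were 87.9% of the 50-nt ends and the window around position 98 held 32.0%. That profile differed from the one after heat shock by 6.64% of its ends and from the one before by 23.7%. With the LNA against Ezh2, internal ends were 86.8% and the window held 22.7%, and the profile differed by 14.4% from the one after heat shock and by 20.6% from the one before. For scale, the 2 longer-read libraries before heat shock differed from each other by 24.1% and the 2 after it by 28.5%, with 568 to 2746 reads each. In the longer reads, the B2 LNA library had 89.0% internal ends (95% Clopper-Pearson interval 87.3 to 90.6%, 1428 reads) and the Ezh2 LNA library 80.0% (70.2 to 87.7%, 90 reads). No test was made, because each LNA had 1 profile of each read type.

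ES cells, which the series text lists without a heat shock or a transfection, also had many ends near position 98. In their 50-nt profile, the window around it held 36.8% of ends, with 15.3% at position 98 and 12.4% at position 99. Internal ends were 74.9%, against 72.0% in fibroblasts before heat shock, and the start window held 11.6%. This profile came from 1 library, and the labels place it in another cell type.

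Ezh2, the catalytic subunit of Polycomb repressive complex 2, was profiled to see where it lies on chromatin before and after heat shock. Of 1792 bins of 10 kb tested, 96 held more Ezh2 reads after heat shock and 763 held fewer (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p threshold of 0.05, n = 2 per condition). On chromosome 5 (24940001 to 24950000, mm9) there were 33 and 119 reads after heat shock and 0 in both libraries before it (edgeR adjusted p = 0.00118). Chromosome 4 (29880001 to 29890000) had 27 and 55 reads after and 0 before. On chromosome 12 (20270001 to 20280000) the counts were 67 and 21 before heat shock and 0 after it (edgeR adjusted p = 0.00323), and on chromosome 13 (12980001 to 12990000) 48 and 34 before and 0 after. In 853 of the 859 bins (99.3%) a whole condition listed no reads. Such bins were 47.6% of the 1792 tested, and 6 of the 939 with reads in both conditions passed. The count therefore mostly reflects which bins each condition lists at all. The files list only reads that passed the authors' filter, so an empty bin is no measured zero and no fold is given. Within the 424 stretches that the files listed in both conditions, 0 passed the edgeR test, with 2 at an unadjusted p under 0.05, and 0 passed with DESeq2. After TMM, which centres the changes near 0 and so hides a change common to all stretches, their median log2 change was 0.09. The 10th to 90th percentile ran from -0.83 to 0.97. On the same 1792 bins, the count was 1 without the first library before heat shock, 6 without the second, and 774 and 902 without the first and second after it; with the low-count filter applied anew to the libraries left, 4913 to 8737 bins were tested and 0 to 6 passed, with 34 to 1164 at an unadjusted p under 0.05 (DESeq2 was not run there). With a replicate block, which here separates the sequencing runs, 1 bin was higher and 2 were lower, and with 1 read kept per position and strand 6 were higher and 61 lower. The count was 0 of 126 bins at a mean of 50 reads, with 0 at an unadjusted p under 0.05 (that filter was not run with DESeq2), it was 1 without a low-count filter, and DESeq2 on the bins gave 524.

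**Figure D3:**
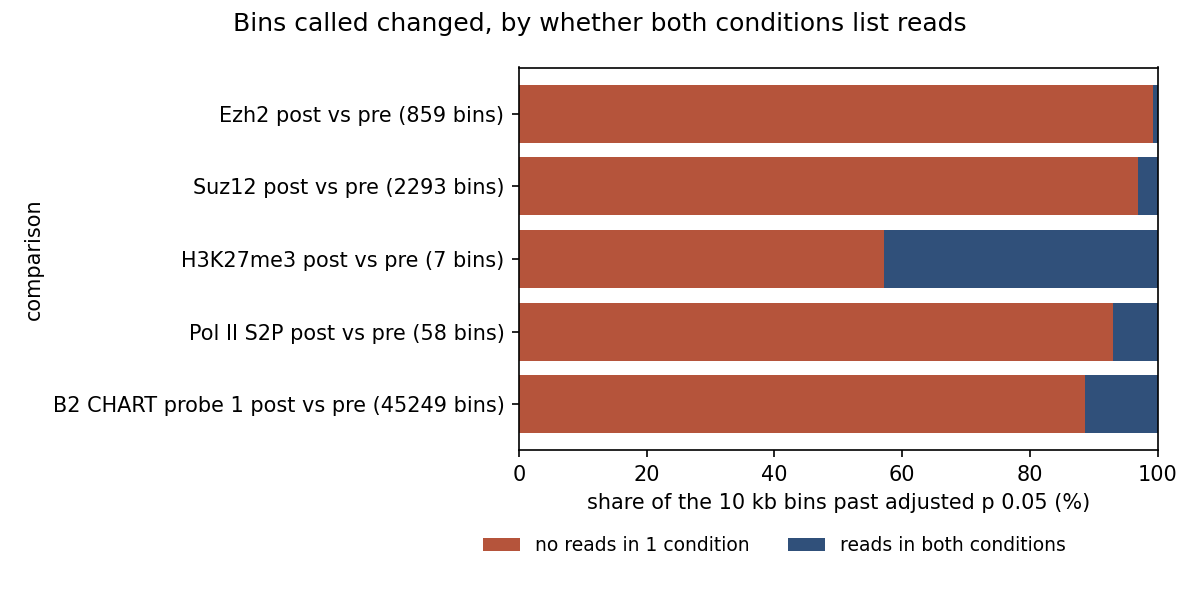
Share of the 10 kb bins past the adjusted p threshold of 0.05 (percent, horizontal axis) in which 1 condition lists no reads or both list reads, 1 bar per comparison (vertical axis). Bins without reads in 1 condition make up 99.3% for Ezh2, 96.9% for Suz12, 57.1% of 7 bins for H3K27me3, 93.1% for Pol II S2P and 88.7% for B2 CHART probe 1. Among all bins tested, those without reads in at least 1 condition make up 47.6%, 65.1%, 5.28%, 68.1% and 68.8% in turn.

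Suz12, a core subunit of the same Polycomb complex, was profiled for the same question. Of 3414 bins tested, 1284 held more Suz12 reads after heat shock and 1009 fewer (edgeR's quasi-likelihood test, n = 2 per condition). Chromosome 7 (34040001 to 34050000) had 131 and 134 reads after heat shock and 0 before it (edgeR adjusted p = 2.59e-16), and chromosome 13 (12980001 to 13010000) had 250 and 132 after and 15 and 5 before. Chromosome 10 (109140001 to 109150000) had 71 and 59 reads before and 0 after (edgeR adjusted p = 1.63e-09). A whole condition listed no reads in 2222 of the 2293 bins (96.9%). Such bins were 65.1% of the 3414 tested, and 71 of the 1192 with reads in both conditions passed. Within 736 stretches listed in both conditions, 2 fell after heat shock by edgeR and 2 by DESeq2, with 25 at an unadjusted edgeR p under 0.05. These lay on chromosome 19 (53838076 to 53838359; log2 change -2.16, edgeR adjusted p = 0.0167, 59 and 39 reads after against 163 and 236 before) and on chromosome 9 (65044382 to 65044620; log2 change -2.69, edgeR adjusted p = 0.0411, 16 and 13 against 54 and 123). After TMM centring, the median log2 change of the stretches was -0.01, with the 10th to 90th percentile from -1.05 to 0.74. On the same 3414 bins, the count was 0 without the first library after heat shock, with 2277 at an unadjusted p under 0.05 (DESeq2 was not run there), and 2248 to 2531 without each of the others. With the low-count filter applied anew, 6960 to 9770 bins were tested and the count was 0 without the second library after heat shock (3986 at an unadjusted p under 0.05), 5 without the first and 559 without the second before it. At a mean of 50 reads 2 bins passed, and with 1 read kept per position and strand 314. The balance turned to 1494 higher and 3553 lower without a low-count filter, to 194 and 406 with a replicate block, and, with the filter applied anew, to 1057 and 1775 without the first library before heat shock and 238 and 321 without the second.

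H3K27me3, the repressive histone mark that Ezh2 deposits, passed the test in 7 of 322 bins, 5 with more reads after heat shock and 2 with fewer (edgeR's quasi-likelihood test, n = 2 per condition). All 7 are named here, after their values were seen for those outside the naming rule. On chromosome 13 (77570001 to 77580000) the log2 change was -5.07 (edgeR adjusted p = 4.99e-06), with 4 and 6503 reads before and 0 and 112 after. On chromosome 7 (111570001 to 111580000) it was -3.21 (edgeR adjusted p = 0.00261), with 0 and 327 reads before and 0 and 16 after. Without TMM, whose factors ran from 0.244 to 3.39 here, these changes were -2.12 and -0.60 (edgeR adjusted p = 0.998 for both). Nearly all reads of both bins before heat shock came from the second library, and the test gave a bin's own spread between libraries no weight. On chromosome 15 (78170001 to 78180000) the log2 change was 5.46 (edgeR adjusted p = 0.0269), with 0 and 2 reads before and 7 and 50 after. The other 4 listed no reads before heat shock and had 8 and 32 reads on chromosome 11 (21350001 to 21360000), 13 and 25 on chromosome 11 (84400001 to 84410000), 12 and 24 on chromosome 12 (87830001 to 87840000) and 8 and 48 on chromosome 1 (90110001 to 90120000). DESeq2 gave 19 higher and 0 lower, and edgeR gave 0 with file totals in place of TMM, 0 without a low-count filter and 0 at a mean of 50 reads, with 19, 771 and 1 at an unadjusted p under 0.05 (DESeq2 was not run with these). Within 111 stretches listed in both conditions, 0 passed by edgeR or DESeq2 and 0 had an unadjusted p under 0.05 with either. The files listed 145730 and 3213842 reads before heat shock and 117426 and 238265 after it. On the same 322 bins, 3 were higher and 4 lower without the first library before heat shock, 2 and 0 without the second, 6 and 6 without the second after it, and 0 passed without the first after it, with 5 at an unadjusted p under 0.05. With the low-count filter applied anew, 571 to 4501 bins were tested and the splits were 0 and 4, 2 and 35, 0 and 4, and 0 in turn, with 671 at an unadjusted edgeR p under 0.05 for the last (DESeq2 was not run without a library). With a replicate block, which separates the sequencing runs, 0 were higher and 3 lower, and without the stretches on chromosomes 2 and 9 that hold many ChIP reads 98 were higher and 2 lower.

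Pol II S2P, the elongating form of the polymerase, was profiled to see where transcription differed after heat shock. Of 3624 bins tested, 7 held more reads after heat shock and 51 fewer (edgeR's quasi-likelihood test, 6 libraries in 1 fit, n = 2 per condition), with 1295 at an unadjusted p under 0.05. Without TMM the split was 27 higher and 22 lower, with DESeq2 278 higher and 489 lower, and with a replicate block, which separates the sequencing runs, 62 higher and 242 lower. Chromosome 5 (150420001 to 150440000) had 209 and 126 reads after heat shock and 0 before it, and chromosome 7 (106490001 to 106500000) had 74 and 62 after and 0 before. Chromosome 2 (117940001 to 117960000) had 55 and 87 reads before and 0 after. Each of these had an edgeR adjusted p = 0.0498. A whole condition listed no reads in 54 of the 58 bins (93.1%). Of the 3624 tested, 68.1% listed no reads in at least 1 of the 2 conditions, and 4 of the 1156 with reads in both passed. Within 267 stretches listed in both conditions, 0 passed the edgeR test, with 4 at an unadjusted p under 0.05, and 0 passed with DESeq2. After TMM centring, their median log2 change was -0.10, with the 10th to 90th percentile from -0.90 to 0.79. On the same 3624 bins, the count was 0 without either library before heat shock, with 1127 and 887 at an unadjusted p under 0.05, 415 and 622 without the first and second after it, and 216 and 208 without the first and second B2 LNA library; with the low-count filter applied anew, 6414 to 13301 bins were tested and 44 to 159 passed. By edgeR 0 of 847 bins passed with only the 4 libraries compared, 0 of 2414 at mapping quality of 20 or more and 0 of 4699 in 50 kb bins, with 218, 876 and 1411 at an unadjusted p under 0.05 (DESeq2 was not run on these).

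Cells labelled with the LNA against B2 RNA, an RNA known to bind and inhibit RNA polymerase II, were used to ask whether that LNA altered Pol II S2P. The level of B2 RNA in these cells was not measured against a control here. In the same fit, 0 of 3624 bins differed between B2 LNA cells and cells before heat shock, with 1203 at an unadjusted p under 0.05. DESeq2 gave 68 bins higher and 45 lower, edgeR without TMM gave 198 higher and 28 lower, and edgeR with a replicate block, which separates the sequencing runs, gave 26 and 8. Within 1029 stretches listed in both conditions, 0 passed the edgeR test, with 10 at an unadjusted p under 0.05, and 0 passed with DESeq2. After TMM centring, their median log2 change was 0.03, with the 10th to 90th percentile from -0.81 to 0.90. On the same bins, 0 passed without either library before heat shock, with 744 and 704 at an unadjusted p under 0.05, 726 and 804 passed without the first and second after it, and 10 and 5 without the first and second B2 LNA library. With the low-count filter applied anew the counts were 2 to 695. With only the 4 libraries compared, 1366 bins were higher and 84 lower. Across the 3624 bins, the log2 changes with heat shock and with the B2 LNA had a Spearman correlation of 0.49 and a Pearson correlation of 0.52. Unchanged groups simulated against the same control libraries gave 0.51 and 0.57. The covariance was 9.35 against a simulated 2.03 ± 0.11 (SD, 20 simulations), while 52.2% of bins changed in the same direction against a simulated 67.6%. The simulation removed no reads per condition. Of the real bins, 68.1% listed no reads in at least 1 condition compared for heat shock and 42.5% for the B2 LNA. These values therefore do not decide whether the 2 changes were related. Bins are not independent replicates.

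B2 CHART asked which chromatin B2 RNA lies on and whether heat shock changes it. With probe 1, 28594 of 58357 bins held more reads after heat shock and 16655 fewer (edgeR's quasi-likelihood test, n = 2 per condition). Chromosome 10 (61200001 to 61220000) had 637 and 295 reads after heat shock and 0 before it (edgeR adjusted p = 1.22e-13), and chromosome 4 (118200001 to 118210000) had 489 and 227 after and 0 before. Chromosome 2 (32210001 to 32240000) had 5423 and 88 reads before and 0 after (edgeR adjusted p = 2.39e-09), X (100680001 to 100690000) had 3012 and 24 before and 0 after, and chromosome 1 (12430001 to 12450000) had 580 and 392 before and 0 after. The test gave a bin's own spread between libraries no weight, so counts as uneven as those on chromosome 2 and X could pass. A whole condition listed no reads in 40125 of the 45249 bins (88.7%). Such bins were 68.8% of the 58357 tested, and 5124 of the 18232 with reads in both conditions passed. Among 17466 bins with reads in every library, 1376 were higher and 1039 lower. Within 10536 stretches listed in both conditions, 1 passed the edgeR test, with 265 at an unadjusted p under 0.05. That was chromosome 6 (47707375 to 47708388; log2 change 4.09, edgeR adjusted p = 0.0315, 32 and 57 reads after and 16 and 3 before). DESeq2 passed 0, with 304 at an unadjusted p under 0.05. After TMM centring, the median log2 change of the stretches was -0.06, with the 10th to 90th percentile from -1.02 to 0.97. In simulated data on such stretches a 4-fold change was recovered in 4.44% of 45 and a 16-fold change in 85.7% of 49, so most 4-fold changes would have been missed by this test. The bin count was 38714 on the same bins without the first library after heat shock, and 27128 with the low-count filter applied anew.

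Probe 2, with 1 library before and 1 after heat shock, had no replicate and no test. Of 16468 bins measured with both probes, 46.7% changed in the same direction, with a Spearman correlation of -0.06 across bins, which are not independent replicates. Of the bins called for probe 1 and measured with probe 2, 3047 of 7461 higher ones were also higher with probe 2 and 2369 of 4216 lower ones were also lower. Among the 1120 bins with reads in both conditions of both probes, 46.6% changed in the same direction.

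The lists were also joined into islands, runs of reads with gaps of at most 600 bp. B2 CHART probe 1 islands numbered 34309 before heat shock, covering 63.9 Mb, and 56716 after it, covering 125 Mb. Probe 2 islands numbered 18373 (32.3 Mb) and 16115 (21.5 Mb). Of the probe 1 islands of a library, 98.4% on average overlapped the islands of its replicate and 24.2% those of a library of the other condition. For the ChIP libraries these means were 67.8% between replicates and 11.2% between conditions, but among islands of at least 20 reads they were 33.9% and 32.2%. Over all islands, shuffled ones overlapped in 12.5% and 12.6% for probe 1 and in 0.991% and 0.994% for the ChIP libraries. The probe 1 and ChIP means are therefore not on the same scale. Ezh2 islands overlapped Suz12 islands 7.07 times as often as shuffled islands did before heat shock and 6.72 times after it, H3K27me3 islands 4.61 and 6.43 times, and Pol II S2P islands 5.89 and 5.95 times. Probe 1 islands overlapped Ezh2 islands 1.04 and 1.03 times as often as shuffled ones, Suz12 islands 1.33 and 1.20 times, H3K27me3 islands 0.913 and 0.831 times and Pol II S2P islands 0.889 and 0.999 times. For probe 2 these values were 1.60 and 1.78 for Ezh2, 2.17 and 1.86 for Suz12, 1.59 and 0.946 for H3K27me3 and 1.61 and 1.58 for Pol II S2P. The islands of the probes overlapped each other 2.17 and 1.93 times as often as shuffled ones. Over reads of mapping quality 20 or more, probe 1 islands overlapped Suz12 islands 1.11 times as often as shuffled ones, before and after heat shock. For probe 2 and Suz12 the values were then 1.89 and 1.43, and for Ezh2 and Suz12 they were 9.06 and 7.28. Shuffled islands could land anywhere on their chromosome, also where no read can lie, so a ratio above 1 can arise without a link between assays. These ratios describe the lists and carry no test.

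**Figure D4:**
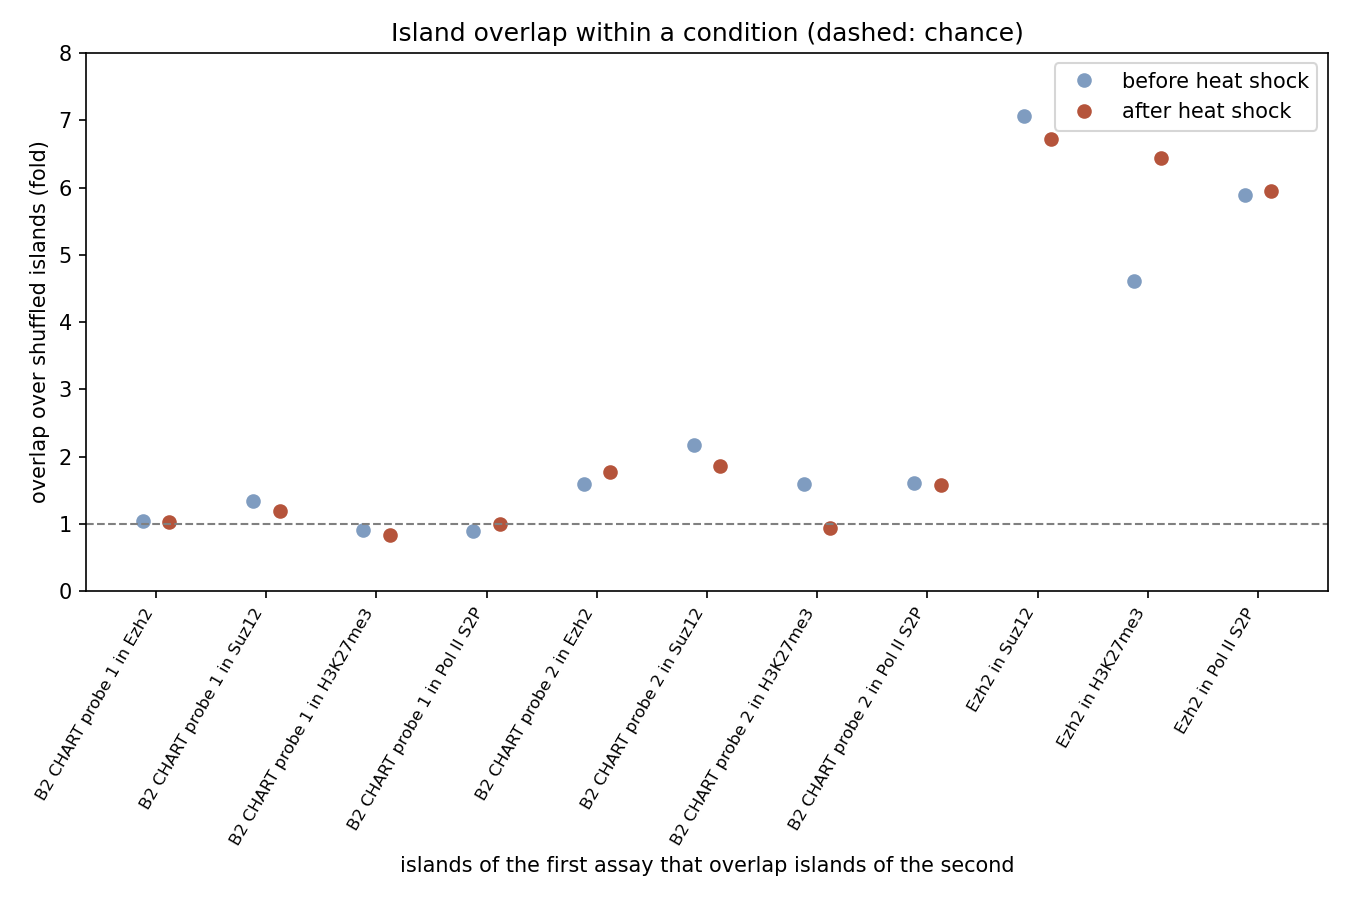
Overlap of islands of the first assay with islands of the second (named along the horizontal axis), as a fold over shuffled islands (vertical axis), with a point before and a point after heat shock. The dashed line, titled chance, marks 1, the level of shuffled islands, which could also land where no read can lie. Ezh2 islands lie at 4.61 to 7.07, and B2 CHART probe 1 islands at 0.831 to 1.33.

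Setting the change of B2 CHART beside the change of each chromatin mark asked whether they moved together across regions. With probe 1 the Spearman correlation was -0.11 for Ezh2 over 709 bins, 0.00 for Suz12 over 1593, 0.05 for H3K27me3 over 119, -0.01 for Pol II S2P after heat shock over 1171 and 0.04 for Pol II S2P with the B2 LNA over 1171. The Pearson values were -0.11, 0.01, 0.13, 0.01 and 0.02. For Ezh2 the sign depended on the setting, with 0.162 for probe 2 over 572 bins, 0.0137 in 50 kb bins and 0.0871 over the 160 bins with reads in both conditions of both assays. The sign of the others turned with the setting too, with values from -0.0995 to 0.00 for Suz12, -0.0777 to 0.479 (the latter over 10 bins) for H3K27me3, -0.0943 to 0.0668 for Pol II S2P after heat shock and -0.111 to 0.112 with the B2 LNA. These 5 relations are across bins, which are not independent replicates, so no p is given.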

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

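The tests of which condition was empty, of both probes moving together, of regions with reads in both conditions, of the start of B2 RNA, of a single library and of small islands, by reads or by distinct positions, were chosen after the result they bear on had been seen, and the tests of a 200 bp grid and of duplicates in probe 2 before.

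Ends just upstream of B2 RNA, at positions -5 to -1, lie outside the windows compared and were listed in all 6 longer-read libraries. They made up 11.97% and 14.4% of ends in the libraries before heat shock, 8.39% and 8.63% after it, 7.42% with the B2 LNA and 7.78% (7 of 90 reads) with the Ezh2 LNA.

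In 5 comparisons, most regions called changed listed no reads in a whole condition. For H3K27me3 these were 4 bins, all empty before heat shock, and depth was not tested there. A difference in depth as the only cause would empty bins nearly all in the shallower condition. That is argued against for Suz12 and CHART, where 43.9% and 34.8% of such bins were empty in the condition with fewer of them. A part played by depth is not excluded there. Depth stays open for Ezh2 and Pol II S2P, where 10.9% and 13.0% were too few to decide. Their file totals, larger in the condition with more empty bins, are not library depth. For CHART, a filter that kept reads inside fixed 200 bp windows is argued against, since the left-most read starts showed a resultant length of at most 0.00723 on such a grid. Removal by the authors, separately in each condition, of reads outside enriched stretches may be part of the pattern for CHART. There 3.52% of probe 1 islands after heat shock held under 20 reads, where scattered background would leave many. For ChIP the 2 measures disagree. At most 9.08% of the islands of any ChIP group held 2 distinct 5′ read positions or fewer, but 17.6 to 95% held under 20 reads. Such removal therefore stays open for ChIP. True changes of occupancy with heat shock stay open beside it, also for CHART, where 46.4% of the bins called for probe 1 moved the same way with probe 2 but probe 2 had 1 library per condition.

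The 2 CHART probes did not change in the same direction across bins. Duplicate reads in probe 2 stay open, although 45.5% of bins moved the same way with 1 read kept per position and strand. Of 32464 probe 2 bins, 13767 listed reads only after heat shock and 15722 only before it. Removing duplicates cannot turn the direction of such bins, so this test could hardly come out otherwise. Islands listed separately for each probe and condition stay open. Where both probes had reads in both conditions 46.6% of bins moved the same way, but such a bin can still hold different islands per condition. For probe 1, 2415 of 17466 bins with reads in every library passed, against 1 of 10536 stretches listed in both conditions. With 1 probe 2 library per condition, its spread between libraries could be large and was not measured, and a difference in what the probes capture was not tested.

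The window around position 98 held a larger share of 5′ ends after heat shock. A loss of ends at the start of B2 RNA, which would raise every internal share alike, stays open: the share among internal ends was 1.83 times as high after heat shock in the pooled 50-nt profiles, which have no spread, but did not separate the conditions in the longer reads. A single library may carry the rise among internal ends, where the lower longer-read library after heat shock stood at 22.2%, inside the 95% intervals of both before it (16.2 to 23.9% and 20.7 to 27.1%), and the other at 41.9%. Of all ends the lower library held 19.2%, above the intervals of both before it (12.5 to 18.5% and 13.6 to 18.0%), but its own interval (16.7 to 21.9%) overlaps them, so this measure does not decide. An effect of heat shock on cutting near position 98 stays open as a hypothesis, with 2 libraries per condition too few to decide.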

How the results depend on the processing

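Chosen after the data were seen were the tests with mapping quality of 20 or more, without the stretches on chromosomes 2 and 9, within stretches listed in both conditions, over bins with reads in every library, over regions with reads in both conditions of both assays, with the crossed block, with probe 2 duplicates removed and, for left-out libraries, with the bins held fixed. Of the alternatives, 88 stayed within the limits set and 103 moved. Limits were 1.5 times for a count and 1 SD for a share or a mean overlap. For correlations and for the agreement of the 2 probes they were sampling margins that treat bins as independent, which they are not. Unless stated, the cause was not tested.

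Counts of changed bins were 859 for Ezh2, 2293 for Suz12, 7 for H3K27me3, 58 for Pol II S2P after heat shock, 0 for Pol II S2P with the B2 LNA (1203 at an unadjusted p under 0.05) and 45249 for CHART probe 1. DESeq2 moved Ezh2 to 524, H3K27me3 to 19, Pol II S2P to 767 and the B2 LNA to 113. Without TMM H3K27me3 gave 0 (19 at an unadjusted p under 0.05) and the B2 LNA 226. Without a low-count filter Ezh2 gave 1, Suz12 5047, H3K27me3 0 (771 unadjusted), Pol II S2P 285 and the B2 LNA 97. At a mean of 50 reads, with fewer bins tested, Ezh2 gave 0 (0 unadjusted), Suz12 2, H3K27me3 0 (1 unadjusted), Pol II S2P 21 and CHART 11356. In 5 kb bins H3K27me3 gave 2 and Pol II S2P 374. In 50 kb bins Ezh2 gave 89, H3K27me3 4, Pol II S2P 0 (1411 unadjusted) and CHART 15120. With 1 read per position and strand the counts were 67 for Ezh2, 314 for Suz12, 61 for H3K27me3, 403 for Pol II S2P and 10 for the B2 LNA. With only the 4 libraries compared, Pol II S2P gave 0 (218 unadjusted) and the B2 LNA 1450. On bins, DESeq2 was run with the default filter alone.

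At mapping quality of 20 or more H3K27me3 gave 17 and Pol II S2P 0 (876 unadjusted). Without the stretches on chromosomes 2 and 9 they gave 100 and 199. Within stretches listed in both conditions edgeR gave 0 for Ezh2 (2 unadjusted), 2 for Suz12, 0 for H3K27me3 (0 unadjusted), 0 for Pol II S2P (4 unadjusted) and 1 for CHART, and DESeq2 gave 0, 2, 0, 0 and 0 (1, 0, 3 and 304 unadjusted for the zeros in turn). Over bins with reads in every library edgeR gave 0 for Ezh2 (15 unadjusted), 4 for Suz12, 0 for H3K27me3 (2 unadjusted), 0 for Pol II S2P (34 unadjusted) and 2415 for CHART.

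Leaving out each library in turn, with the low-count filter applied anew and so other bins tested, gave 0 to 6 for Ezh2, 0 to 2832 for Suz12, 0 to 37 for H3K27me3, 44 to 159 for Pol II S2P, 2 to 695 for the B2 LNA and 27128 to 52077 for CHART probe 1. The lone library of a group was then assumed to vary like the others. On the bins tested with all libraries, which the left-out library helped to choose, it gave 1 to 902 for Ezh2, 0 to 2531 for Suz12, 0 to 12 for H3K27me3, 0 to 622 for Pol II S2P, 0 to 804 for the B2 LNA and 38714 to 45048 for CHART probe 1. For the longer reads, leaving out each library gave differences of 8.94 to 19.98 points for internal ends, 3.70 to 20.3 for the window around position 98 and 0.353 (without the second library after heat shock) to 20.1 for these among internal ends.

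Same-numbered libraries came largely from the same sequencing run or instrument, except for Suz12, whose libraries share 1 lane, and the labels name no shared culture or day. The correlation of their deviations was 0.27 for Ezh2, -0.02 for Suz12, -0.32 for H3K27me3, 0.10 and 0.12 for the Pol II S2P comparisons and -0.05 for CHART. With a replicate block, which separates the sequencing runs except for Suz12, the counts were 3 for Ezh2, 600 for Suz12, 3 for H3K27me3, 304 for Pol II S2P and 34 for the B2 LNA, and CHART gave 44244. With crossed numbers the block gave 19 for H3K27me3.

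With duplicates removed, 45.5% of bins moved the same way with both CHART probes. Mean overlap of ChIP islands between replicates was 44.1% with gaps of at most 200 bp and 33.9% for islands of at least 20 reads, and between conditions 32.2% for the latter. For CHART probe 1 replicates these were 95.8% and 78.3%. The Spearman correlation of CHART and Ezh2 changes was 0.0137 in 50 kb bins, 0.162 with probe 2 and 0.0871 over regions with reads in both conditions of both assays. With probe 2 it was 0.0668 for Pol II S2P and -0.0940 for the B2 LNA. Over regions with a mean of 50 reads, Pol II S2P had 7 and got no value. Internal and site shares of the 50-nt reads stayed within the limits set, but such limits on shares were wide. Between the 2 longer-read libraries of a condition the SD reached 7.80 points for internal ends and 11.8 for the site. For the site among internal ends, the longer-read difference of 10.2 points fell to 0.353 without the second library after heat shock. That fall also counted as within the limits. Staying within them therefore does not show that a share is stable.

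Not run were the alternatives for gene regions and gene lists, and a limit on the last position along B2 RNA that lies beyond the end of every profile. Library depth is not known from the file totals. In data simulated on the 10 kb bins, a 4-fold change was recovered in 0 to 18.2% of regions across the comparisons, so changes of that size would mostly have been missed.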

Other observations

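All comparisons in this part were chosen after the data had been seen.

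A neighbourhood on chromosome 13 appeared among the named regions of both Polycomb subunits, in opposite directions. The bin from 12980001 to 12990000 listed 48 and 34 Ezh2 reads before heat shock and 0 after it. The region from 12980001 to 13010000 listed 250 and 132 Suz12 reads after heat shock and 15 and 5 before. Across 514 bins tested for both, the changes of Ezh2 and Suz12 had a Spearman correlation of -0.11. For H3K27me3 and Pol II S2P it was 0.31 over 186 bins, the highest of the 6 pairs of ChIP assays by Spearman's rho, with a Pearson correlation of 0.12. Bins are not independent replicates, and no p is given.

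Reads of a CHART probe 1 library fell mostly in the islands of its own condition. Between 75.0 and 98.96% lay inside the islands of the other replicate, and 11.96 to 24.1% inside those of the other condition. No chance level stands beside these shares. The lists hold only reads that passed the authors' filter, and 3.52% of probe 1 islands after heat shock held under 20 reads. The shares therefore describe the lists and cannot separate a removal of reads in each condition from a change of B2 RNA on chromatin.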
